A study of Mus musculus with 8 samples.

How the data were processed

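Kidney RNA of 8 CD-1 mouse samples was measured on one-colour (Cy3) Agilent mouse miRNA arrays, 4 from mice given physiological serum (control) and 4 from mice given tacrolimus at 1 mg per kg per day for 28 days, per the labels. RNA input was 0.1 µg and the RNA integrity number was 9 for every sample, per the labels' characteristics. The labels do not say whether each replicate is a separate mouse, so p-values measure only the spread between these samples, which may be technical. The kit named for labelling in the labels is one for mRNA, and how the miRNA was labelled is not given in the sources used here.

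The authors deposited the scanner output of each array, made with Feature Extraction 10.7.3.1 per the file headers. Its values are spot intensities on a linear scale. The processed intensity has the local background subtracted and spatial trends removed by that software, per the file headers, and nothing in the files scales one array to another. The authors' deposited value table was set against the same arrays and equalled the software's total gene signal in 100% of cells (tolerance 1e-06). It is therefore a linear intensity that is not normalized between arrays, with miRNAs that were not detected listed at 0.1, which is also the median of the table in both groups. Its scale, centring and direction are thereby known. The submitters' processing notes name limma with no version or role.

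From the deposited intensities the following was computed with R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table. The array holds 45364 features, of which 40920 are spots for 1023 mouse miRNA names, in 2645 probes of 10 to 40 spots each. A further 57 names are viral miRNAs and were kept out of the tests, as were control features. Spots marked by the software as non-uniform or as population outliers were left out (7.36% to 11.2% of miRNA spots per array), no spot was saturated (0), and the remaining spots of a probe were averaged. A probe counted as detected on an array if at least 0.5 of its kept spots were well above background. Over all arrays 12.9% of probes were detected, so each array was scaled to the 75th percentile of the 252 probes detected on all 8 arrays rather than of all probes. A floor was then set at the median over arrays of the lowest scaled signal of a detected probe (-5.96 on the log2 scale), and log2 was taken. A signal of 0 on this scale equals the 75th percentile of the detected probes. Each miRNA was represented by its brightest probe. A miRNA was tested if that probe was detected on at least 4 of the 8 arrays, whatever their group, which left 194 miRNAs and put 829 aside. Of 156 tested miRNAs with another probe that passed the same filter, 12 had probes whose differences had opposite signs. miRNA names are those of the array's design, and 10 of the 194 tested names carry a mark of an older version of the name.

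Groups were compared with limma (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 194 miRNAs and a threshold of 0.05. SE and intervals of log2 differences are those of limma, with 9.17 degrees of freedom. For lists of miRNAs, camera with a preset correlation of 0.01 tested whether members differed from the other tested miRNAs. Camera with an estimated correlation was run beside it, and fry, which tests a list against no change rather than against the other miRNAs. All were adjusted over the 15 lists with at least 3 tested members. Single values per array, such as a list mean, were compared with exact two-sided permutation tests, for which 4 against 4 arrays allow no p below 0.0286.

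The 18 lists, the tests and the rule for named miRNAs were written before the data were examined. By that rule the text names up to 12 risers and 12 fallers past the threshold, filled up to 24 by the smallest unadjusted p. It also names miR-21a-5p, miR-199a-5p, miR-199a-3p and miR-214-3p whatever their values, the called members of each list (at most 4) or its 2 members of smallest p, 7 cell and tissue markers, and any miRNA detected on every array of one group and on no array of the other, of which there were 0. This gave 43 tested miRNAs. miRNAs outside this rule are marked where they appear. The lists were fibrosis-promoting, fibrosis-restraining, tubule epithelium, endothelium and vascular smooth muscle, leukocyte, erythrocyte, striated muscle, neural and endocrine, liver, NF-kappaB and inflammation, p53 with hypoxia and cell stress, calcineurin-NFAT linked, and Dlk1-Dio3 cluster miRNAs, the miR-200, miR-30, let-7 and miR-29 families, and the miR-17 cluster with its paralogous clusters. Neighbouring genes and host genes of miRNAs were read by name from a RefSeq gene table of assembly GRCm38.p6. The array headers name an older mouse assembly, so no coordinates are given.

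The steps were tested on simulated data with known answers, drawn 100 times for the 194 miRNAs from their means and spreads. For the comparison of tacrolimus with control, 81.8% of 20 miRNAs changed by 0.5 (log2) and 96.4% of 20 changed by 1 were recovered, and 4.02% of calls were false. With no change, 4% of simulations gave a call, and 6% gave a list past the threshold. These simulations draw miRNAs independently, which real miRNAs are not.

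The alternatives were normexp background correction (offset 50), quantile normalization, the 75th percentile of all probes, scaling by the median, no scaling, no filter, detection on all 8 arrays, a floor 2 times as high, the mean of a miRNA's probes, total gene signal, the authors' value table, eBayes with trend and robust estimation, array quality weights, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were leaving out control 1 and tacrolimus 4 (the widest spreads of negative control signals), the miR-451a signal as a covariate, and the fibrosis-promoting list without some members (those named in advance, those called, or those also in the leukocyte list). Where arrays were left out, detection, scaling and floor were redone on the remaining arrays, which can shift all differences together. All 8 arrays lay on 1 slide and were scanned in 1 scan.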

Results

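Tacrolimus is a calcineurin inhibitor given against transplant rejection, and kidney injury is a known side effect. The study asked whether treatment with it is accompanied by altered miRNA levels in the mouse kidney. Whole kidneys of CD-1 mice, an outbred stock, were compared after tacrolimus (4 arrays) and after physiological serum (4 arrays). Between 9.60% and 15.2% of the mouse miRNA probes were detected per array, giving 147 to 217 miRNAs, and 194 of 1023 miRNAs were tested. Arrays correlated at 0.987 to 0.997 over the tested miRNAs. The array of tacrolimus 4 detected the fewest miRNAs (147) and had the widest spread of negative control signals (SD 20.01), followed by control 1 (SD 10.5) and control 3 (SD 9.69). It was the 1 array with a quality metric outside the software's range, the additive error estimate (18.5), out of 8 metrics. All control arrays lay in 1 row of the slide and all tacrolimus arrays in the other, so that slide row and treatment cannot be told apart, while each slide column held 1 array of each group. The number of arrays limits the precision.

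The miR-199 and miR-214 miRNAs rose in the kidneys of tacrolimus-treated mice. miR-214-3p rose by 0.69 on the log2 scale (SE 0.137), or 1.62-fold, from -4.67 ± 0.15 to -3.98 ± 0.27 relative to the detected-probe 75th percentile (mean ± SD, n = 4 arrays each). miR-199b-5p rose 1.42-fold, miR-199a-3p 1.40-fold and miR-199a-5p 1.39-fold (log2 0.50, 0.49 and 0.47, SE 0.106, 0.109 and 0.106). With normexp background, where none of these passed the threshold, miR-214-3p stood at 0.30, miR-199b-5p at 0.39, miR-199a-3p at 0.45 and miR-199a-5p at 0.35. miR-214-3p and both arms of miR-199a are described as raised in fibrotic tissue. The genes Mir214 and Mir199a-2 are nearest neighbours within Dnm3os, a transcript antisense to Dnm3, in the RefSeq annotation of GRCm38.p6, while Mir199a-1 lies within Dnm2 and Mir199b within Dnm1. miR-199a-5p and miR-199b-5p are nearly identical in sequence, so their probes may share signal and the values are uncertain as separate measurements. Second probes differed by 0.35 for miR-199a-5p, 0.51 for miR-199b-5p and 0.51 for miR-199a-3p.

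Past the threshold were also miR-1949, which rose 1.46-fold (log2 0.55, SE 0.123) and whose gene lies within Snhg4, and miR-574-5p, which rose 1.42-fold (log2 0.50, SE 0.111) and whose gene lies within Fam114a1 and Tlr6. miR-574-5p was dim, detected on 3 arrays of each group, and a floor 2 times as high put all 8 of its values at the floor (difference 0). With normexp, miR-1949 stood at 0.22 and miR-574-5p at 0.065. Of the 194 tested miRNAs, 6 rose and 0 fell, each with an adjusted p of 0.0476 in limma, and in each of the 6 every tacrolimus array lay above every control array. At an unadjusted p under 0.05 there were 30 miRNAs, 21 higher and 9 lower, where chance gives 9.7 on average. That average hides a wide spread, since regrouping control 1 with tacrolimus 1, 2 and 4 against the rest gave 29. The groups did not overlap for 20 miRNAs, or 5.54 by chance at 2.86% of the 194. Scaling by the median gave 8 calls, 6 higher and 2 lower, the latter being miR-551b-3p and miR-338-3p.

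The calls lay close to the threshold and depended on single arrays. The count in limma was 0 without control 1, control 2, tacrolimus 1 or tacrolimus 4 (22 to 32 miRNAs at an unadjusted p under 0.05). It was 1 without control 3 (miR-551b-3p) and 2 without control 4 (miR-144-3p, chosen after its values were seen, and miR-486a-5p), so that 0 of the 6 calls were kept there. Without tacrolimus 2 it was 2, of which miR-214-3p was 1 of the 6, and without tacrolimus 3 it was 7, with 5 of the 6. Normexp background gave 1 call, which was none of the 6, and quantile normalization gave 2, miR-199a-5p and miR-199b-5p. With slide column, which equals the replicate number, as a block, the differences of the 6 stayed at 0.47 to 0.69. The count in limma was then 0 (lowest adjusted p 0.0607, 31 at an unadjusted p under 0.05). It was also 0 with the 75th percentile of all probes, no scaling, no filter, a floor 2 times as high, the mean of probes, total gene signal, the authors' value table, and trend and robust estimation (2 to 32 at that unadjusted p).

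**Figure D1:**
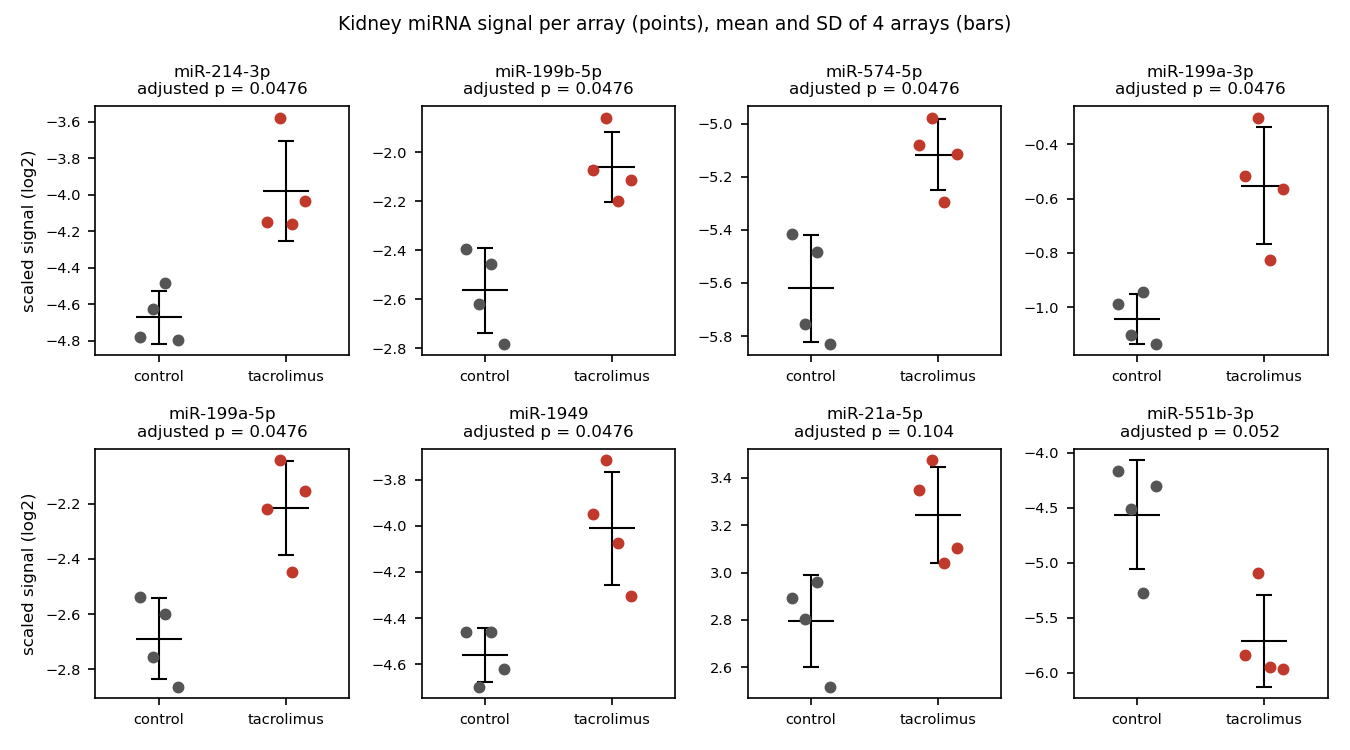
Scaled signal (log2, 0 is the array's 75th percentile of detected probes) of the 6 miRNAs past the threshold, and of miR-21a-5p and miR-551b-3p, which missed it, on the 4 control and 4 tacrolimus arrays. Points are arrays and bars give the mean and SD, with a separate vertical scale for each miRNA. miR-214-3p lies at -4.67 on average in control and -3.98 in tacrolimus kidneys, with no overlap, while miR-551b-3p averages -4.56 and -5.71.

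miR-21a-5p, a miRNA raised in many fibrotic tissues and the brightest of these at 2.79 ± 0.19 in control kidneys, stood at 3.24 ± 0.20 in tacrolimus kidneys (n = 4 each). This difference of 0.45 (SE 0.126) did not pass the test (adjusted p = 0.104, limma), although every tacrolimus array exceeded every control array. Of 15 miRNAs listed in advance as fibrosis-promoting, 10 were tested, 4 rose (miR-214-3p, miR-199b-5p, miR-199a-3p and miR-199a-5p) and 6 did not pass the test. Adjusted over the list alone, 5 rose. Among the rest were miR-155-5p at 0.34, miR-132-3p at 0.09 and miR-34a-5p at -0.18, which were outside the naming rule and chosen after their values were seen. The list's median difference was 0.40 and camera placed it above the other miRNAs (adjusted p = 0.00556). That call was lost with an estimated correlation, which was 0.19 against the preset 0.01 (adjusted p = 0.44, camera). For this list fry gave an adjusted p of 0.0403. The 4 that rose cannot be counted as independent. Mir214 and Mir199a-2 lie within the same transcript, and the probes of miR-199a-5p and miR-199b-5p may share signal. The list includes miR-21, miR-199a and miR-214, chosen with knowledge of this field and study, so it is not independent evidence of its direction. Of its 10 tested members 6 also stand in another list, among them miR-150-5p and miR-155-5p in the leukocyte list, whose mean was 0.45 higher in the tacrolimus kidneys. Without its 4 called members, the median of the other 6 was 0.17 and camera no longer placed them apart (unadjusted p = 0.33). As those 4 were removed for their result, a weaker remainder was built in.

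Of 15 fibrosis-restraining miRNAs, among them the collagen-targeting miR-29 family and the epithelial miR-200 family, 13 were tested and 0 passed the threshold in limma in either direction, with 0 at an unadjusted p under 0.05. Their median difference was 0.04 (adjusted p = 0.923, camera), and it was -0.04 with median scaling. For this list and the miR-200 family, median and mean lay above 0 while camera placed the list below the other miRNAs. miR-29b-3p stood at -0.08 and miR-29a-3p at -0.05, both above 0 without scaling. The miR-29 family had a median of -0.05 over 4 tested members (adjusted p = 0.325, camera) and the miR-200 family one of 0.01 over 7 (adjusted p = 0.768, median below 0 with quantile normalization and median scaling), with miR-200b-5p at -0.17 and miR-141-3p at 0.10.

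Leukocyte miRNAs had a higher mean signal in the tacrolimus kidneys and erythrocyte miRNAs a lower one, although 0 single members of either list passed the threshold over all miRNAs in limma (4 of 9 leukocyte and 3 of 4 erythrocyte miRNAs at an unadjusted p under 0.05). All 9 tested leukocyte miRNAs had a difference above 0, with a median of 0.34. The myeloid miR-223-3p stood at 0.61 (SE 0.161, adjusted p = 0.0911, limma) and the haematopoietic miR-142a-3p at 0.64 (SE 0.213, adjusted p = 0.191, limma). Adjusted over the list alone, 1 of the 9 passed. Camera placed the list above the other miRNAs (adjusted p = 0.00902), a call lost with an estimated correlation (adjusted p = 0.44), and fry gave an adjusted p of 0.0951. The list mean went from -3.99 ± 0.24 to -3.54 ± 0.21 (n = 4 each, exact two-sided permutation p = 0.0571). Of these 9 miRNAs, 3 also stand in another list. The camera call was lost when detection on all 8 arrays was required (adjusted p = 0.0637) and with a floor 2 times as high (adjusted p = 0.0533). Over all settings the list's adjusted p in camera ranged from 6.03e-11, without a filter, to 0.0637. Without a filter most of the compared miRNAs were detected on no array, and the tubule, let-7 and miR-17 cluster lists passed too. The lowest value is therefore no measure of this list's strength.

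Of 4 tested erythrocyte miRNAs, miR-451a differed by -0.67 (SE 0.272) and miR-486a-5p by -0.67 (SE 0.270), each with an adjusted p of 0.273 in limma. The list's median was -0.65, with 1 of 4 members above 0, and its test missed the threshold (adjusted p = 0.0523, camera, and 0.779 with an estimated correlation). That miss depended on the setting, since the list passed in 10 of 24 settings and its adjusted p ranged from 2.34e-05 without scaling to 0.799 with miR-451a as a covariate. Single arrays decided it as well, as it passed without control 3, control 4, tacrolimus 1 or tacrolimus 2 (adjusted p = 0.041, 0.000537, 0.0426 and 0.0275, camera). The control arrays differed widely in these miRNAs, with an SD of 0.63 for miR-451a against 0.20 in the tacrolimus arrays. Without control 4, miR-486a-5p passed the threshold at -0.98. It was dim, detected on 2 control and 3 tacrolimus arrays, and at the floor on tacrolimus 4 (-5.96), so the size of its difference is uncertain.

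**Figure D2:**
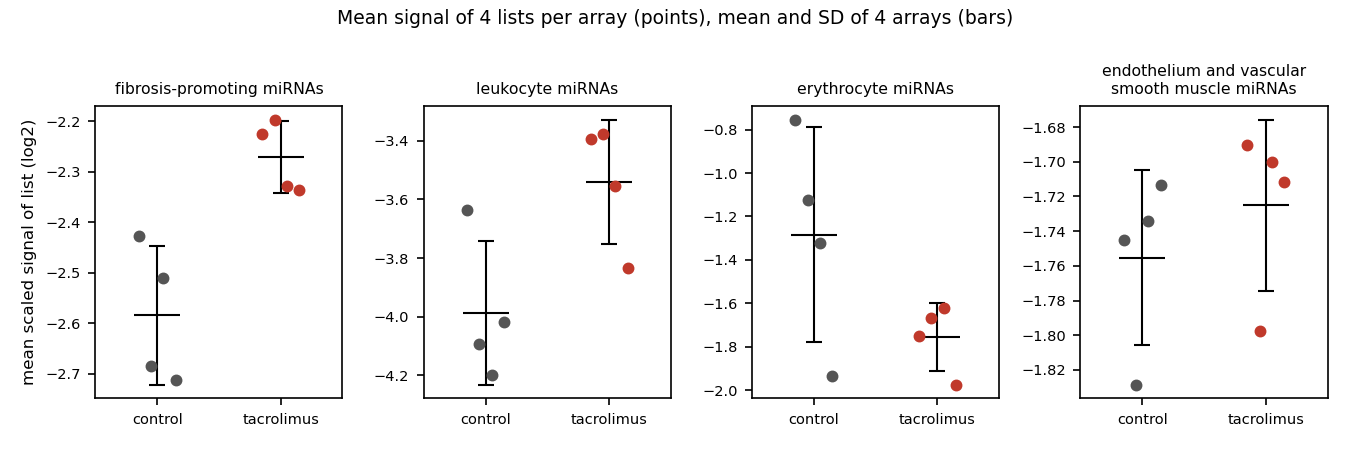
Mean scaled signal (log2) over the tested members of 4 lists on each control and tacrolimus array. Points are arrays and bars give the mean and SD of 4 arrays, with a separate vertical scale for each list. The fibrosis-promoting mean goes from -2.58 to -2.27 and the leukocyte mean from -3.99 to -3.54, while the erythrocyte mean goes from -1.28 to -1.75 and the endothelium and vascular smooth muscle mean from -1.76 to -1.72.

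miRNAs of the kidney's own main cell types did not pass the test. Of 14 tested tubule epithelium miRNAs 0 were called in limma (1 at an unadjusted p under 0.05), with a median of 0.07 (adjusted p = 0.768, camera). Their best known members, miR-192-5p, miR-192-3p and miR-194-5p, stood at 0.13, 0.16 and 0.14, and miR-204-5p at 0.34 (adjusted p = 0.289, limma). Without control 1 and tacrolimus 4, miR-192-5p, miR-192-3p and miR-194-5p lay below 0. With scaling redone there, the median of all tested miRNAs was -0.081, and each of them lay above it. The 9 tested endothelium and vascular smooth muscle miRNAs had a median of 0.02 (adjusted p = 0.948, camera), which was below 0 with quantile normalization and median scaling. Among them the endothelial miR-126a-3p stood at -0.03 (0.12 without scaling), miR-125b-5p at 0.11 and miR-100-5p at 0.18. Of the liver marker miR-122-5p nothing was detected on either group's arrays (0), and the striated muscle marker miR-1a-3p was detected on 0 control and 2 tacrolimus arrays. No member of the liver and striated muscle lists was tested (0 of each).

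The NF-kappaB and inflammation list had a median of 0.32 over 5 tested members, all of which stand in another list. It missed the threshold with camera (adjusted p = 0.0881) and with an estimated correlation (adjusted p = 0.44), and passed it with fry (adjusted p = 0.0403). With camera it passed in 6 of 24 settings, among them normexp, total gene signal and without tacrolimus 4 (adjusted p = 0.0488, 0.0154 and 0.0204), with a range of 2.28e-07 (without a filter) to 0.319. Besides miR-21a-5p it holds miR-146a-5p at 0.32 (SE 0.126, adjusted p = 0.273, limma), a miRNA induced by NF-kappaB. Of 7 tested calcineurin-NFAT linked miRNAs, 1 rose (miR-199b-5p), the median was 0.07 and the list did not stand apart (adjusted p = 0.332, camera), its median falling just below 0 with median scaling. The miR-17 cluster and its paralogs (median 0.08 over 11, adjusted p = 0.375, camera) included miR-20b-5p at 0.20 and miR-19b-3p at 0.11. The let-7 family (median 0.07 over 9, just below 0 with median scaling, adjusted p = 0.332, and 0.0488 with normexp) included let-7i-5p at 0.26, let-7c-5p at 0.13 and let-7b-5p at 0.09. The p53, hypoxia and cell stress list (median 0.09 over 8, adjusted p = 0.768) included miR-34b-5p at 0.31. All 8 tested miR-30 miRNAs lay below 0 (median -0.05, adjusted p = 0.0881, camera), with miR-30c-2-3p at -0.11 and miR-30e-5p at -0.09. Without scaling the family's median was 0.11 and that of all tested miRNAs 0.19. Camera still placed the family below the other miRNAs there (adjusted p = 0.602). The list passed the camera threshold in 5 of 24 settings, which were without control 1, control 2 or tacrolimus 1 (adjusted p = 0.0277, 0.0436 and 0.0426), without control 1 and tacrolimus 4 (0.00718) and with miR-451a as a covariate (0.00283), with a range up to 0.925. The neural and endocrine list had a median of -0.06 over 3 members (adjusted p = 0.352, camera), with miR-7a-5p at -0.07 and miR-128-3p at -0.06, and without scaling the median and both of these lay above 0. Of the Dlk1-Dio3 cluster 2 members were tested, and no list test was made.

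**Figure D3:**
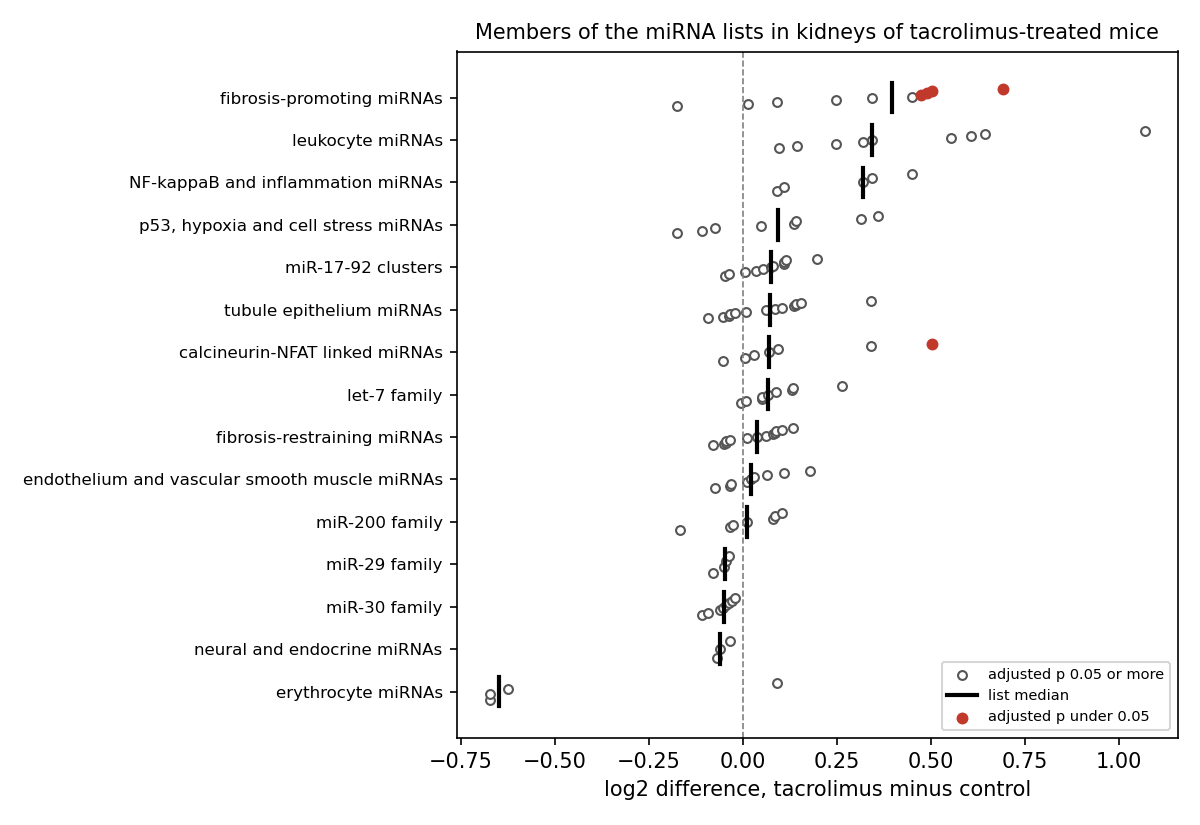
Difference between tacrolimus and control kidneys (log2) of each tested member of 15 lists. Filled points passed the threshold of 0.05 in limma, open points did not, and black bars mark list medians. The fibrosis-promoting median lies at 0.40 and the leukocyte median at 0.34, while the erythrocyte median lies at -0.65.

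Outside the lists, miR-551b-3p stood at -1.15 (SE 0.266) and narrowly missed the threshold (adjusted p = 0.052, limma). The size of this difference depended on the setting, from -1.73 with total gene signal to -0.48 with a floor 2 times as high. It was dim and near the floor of -5.96 in tacrolimus kidneys, detected on 3 arrays of each group, and its scaled signal was -4.56 ± 0.49 in control and -5.71 ± 0.41 in tacrolimus kidneys (n = 4 each). With normexp background it was the 1 miRNA past the threshold, at -0.55 (adjusted p = 0.00205, limma), and over all settings its adjusted p lay between 0.00205 and 0.995. miR-338-3p stood at -0.29 (SE 0.068, adjusted p = 0.0554, limma), miR-652-5p at -0.23, miR-1198-5p at -0.20, miR-378a-3p at -0.19 and miR-677-3p at -0.18. Above 0 were miR-350-3p at 0.27, miR-497a-5p at 0.26 and miR-195a-5p at 0.26, the latter pair being members of one cluster, and miR-28a-5p at 0.18, which turned below 0 with the total gene signal. None of these passed the threshold in limma.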

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

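The count of splits, the list tests of the full lists with a preset or an estimated correlation, the block and the higher floor were planned, and the other tests in this part were chosen after the result they bear on had been seen.

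Of the 35 splits of the 8 arrays into 4 and 4, only the real one (1) gave as many as 6 miRNAs past the threshold, and the highest of the other splits gave 1. That makes the count unlikely by chance in the fit without a block, but does not exclude chance. At an unadjusted p under 0.05, the split of control 1 with tacrolimus 1, 2 and 4 against the rest gave 29 miRNAs, against 30 for the real one. A share of 1 in 35 (2.86%) is the smallest these splits can give, and they take no account of slide column, which as a block left 0 miRNAs past the threshold in limma (31 at an unadjusted p under 0.05). For the lists, 10 of the 35 splits gave at least the 2 lists past the threshold found for the real split, and the highest of the other splits gave 4, so chance cannot be excluded for the list count. The fibrosis-promoting list also passed outside the real split, as with control 1, 3 and 4 and tacrolimus 3 against the rest (adjusted p = 0.0127, camera).

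Of 86 groups of 4 arrays examined for the 43 named miRNAs, 7 held an array far from the others, where chance gives 4.3. Tacrolimus 2 lay 0.82 (log2) above the mean of the other 3 tacrolimus arrays for miR-551b-3p, and differed from that mean by -0.26 for miR-1198-5p and by -0.17 for miR-30e-5p. Tacrolimus 4 differed from the others by -0.39 for miR-451a and by -0.20 for miR-30c-2-3p. Tacrolimus 3 differed by -0.10 for miR-20b-5p, and control 3 differed from the other controls by 0.24 for miR-652-5p. Among the viral probes, which the comparisons do not use, a probe for a mouse cytomegalovirus miRNA (M23-1-3p) and one for a murine gammaherpesvirus miRNA (M1-2-3p) were each detected on 2 tacrolimus arrays and 0 control arrays. Their highest total gene signals were 7.71 and 8.26 against 0.1 in controls, near the lowest signal of any detected mouse miRNA (3.16). Whether viral probe signals come from virus or from cross-hybridisation of other RNA was not tested.

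The fibrosis-promoting list had a higher signal in the tacrolimus kidneys (mean difference 0.31). Against scaling as the cause, the list mean minus the median of the other tested miRNAs of the same array differed by 0.25 (95% interval 0.12 to 0.38, exact permutation p = 0.0286, the smallest 4 against 4 arrays can give). Against raised background on control 1 and tacrolimus 4 as the whole cause, the list mean differed by 0.25 without both arrays (95% interval 0.03 to 0.46, exact permutation p = 0.1, the smallest 3 against 3 can give). Scaling was redone there, and the median difference of all tested miRNAs was -0.081, against 0.039 with all arrays. On the scale of all 8 arrays, leaving both out widens the list difference, since control 1 was the highest control array (-2.43) and tacrolimus 4 the lowest tacrolimus array (-2.34) for this list. Control 3, with a negative control spread close to that of control 1 (SD 9.69 and 10.5), was kept, so the check does not cover it. Against a larger share of endothelial and smooth muscle cells, miR-126a-3p, miR-126a-5p, miR-143-3p and miR-145a-5p differed on average by -0.0039 (95% interval -0.15 to 0.14), when the 4 called miR-199 and miR-214 miRNAs rose by 0.54. Slide row cannot be told apart from treatment, and a change in fibroblasts or pericytes, which may carry these miRNAs, or a larger leukocyte share stays open beside an effect of tacrolimus. Without its members in the leukocyte list, the list had a median of 0.46 over 8 miRNAs (unadjusted p = 0.000414 with camera, and 0.101 with an estimated correlation, against 0.0592 for the full list). This cannot decide on the leukocyte share. The members left out, miR-150-5p (0.25) and miR-155-5p (0.34), both outside the naming rule, lay below the full list's median of 0.40, so leaving them out could not lower it.

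The leukocyte list had a higher mean in the tacrolimus kidneys and the erythrocyte list a lower one, but the leukocyte call was lost with an estimated correlation (adjusted p = 0.44, camera) and the erythrocyte list missed the threshold (adjusted p = 0.0523, camera). Less residual blood predicts lower leukocyte miRNAs too, but all 9 tested ones differed by more than 0, with a mean of 0.45 (95% interval 0.05 to 0.84). With miR-451a as a covariate, camera at the preset correlation still placed that list above the others (adjusted p = 0.00283). These values argue against less blood as the source of the higher leukocyte mean. It is not excluded, since the exact permutation p was 0.0571, and the values do not bear on the erythrocyte part. Chance differences in blood content stay open for the erythrocyte part, because the mean of miR-451a, miR-144-3p and miR-486a-5p gave an exact permutation p of 0.114 (difference -0.66). A hypothesis is that more leukocytes were present at a given blood content, and the mean of miR-142a-3p, miR-142a-5p and miR-223-3p minus that erythrocyte mean on the same array differed by 1.26 (95% interval 0.72 to 1.79, exact permutation p = 0.0286). That contrast cannot decide, since its 6 miRNAs had been seen to move apart, and all 9 tested leukocyte miRNAs were also detected on control kidney arrays.

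The low signal of miR-551b-3p in tacrolimus kidneys (-1.15) lay near the floor of the scale. A common floor narrows such a difference, and with a floor 2 times as high it was -0.48 (adjusted p = 0.242, limma), so its size is not settled. Against raised background on control 1 and tacrolimus 4, the difference was -1.07 without both arrays and with scaling redone (95% interval -1.78 to -0.37), although its adjusted p was then 0.159 in limma with 3 arrays per group. Control 3, whose negative control spread was close to that of control 1, was kept there. Slide row stays open, and an effect of tacrolimus is a hypothesis that may account for the difference, found and tested on the same data.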

How the results depend on the processing

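Leaving out control 1 and tacrolimus 4 together, the miR-451a covariate and shortening a list were chosen after seeing the data. The count of 6 miRNAs moved to 30 and 12 at an unadjusted p under 0.05 and under 0.01. In limma it was 1 with normexp (22 at an unadjusted p under 0.05) and 2 with quantile normalization. It was 0 with the 75th percentile of all probes, no scaling, no filter (1023 miRNAs tested), a floor 2 times as high, the mean of probes, total gene signal, the authors' value table, and trend and robust estimation, with 2, 14, 28, 27, 32, 23, 3 and 31 miRNAs at an unadjusted p under 0.05. It was 1 without control 1 and tacrolimus 4 (39 at that p) and 0 with miR-451a as a covariate (29), and ranged from 0 to 7 when 1 array was left out. It was 8 with median scaling and 7 with array weights, both holding all 6, and 5 with detection on all 8 arrays, all of them among the 6. The cause of these changes was not tested, beyond more miRNAs without a filter and fewer arrays. The 6 called miRNAs kept their sign in all of these settings, except miR-574-5p with the higher floor (0), but with normexp their differences shrank to between 0.065 (miR-574-5p, unadjusted p = 0.483) and 0.45 (miR-199a-3p), with miR-214-3p at 0.30 and miR-1949 at 0.22, and they stayed past the threshold in only 25 of 143 combinations with a setting.

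The count of 2 lists was 0 with an estimated correlation and 2 with fry, 5 with normexp, 10 without a filter, 1 with detection on all 8 arrays, 1 with the higher floor, 4 with the value table and 4 without both arrays. It ranged from 2 to 4 when 1 array was left out, and the cause was not tested. At the preset correlation, the fibrosis-promoting list kept its camera call in all 24 settings in which its membership was kept (adjusted p 1.65e-08 to 0.0494), but it lost the call with an estimated correlation (adjusted p = 0.44). At the preset correlation it also lost it without the 4 miRNAs named in advance (unadjusted p = 0.255) or its 4 called members (0.33), the latter removed for their result. The leukocyte list kept its call in 22 of 24 at the preset correlation (adjusted p 6.03e-11 to 0.0637), and lost it with an estimated correlation (adjusted p = 0.44). In fry, which asks a different question, it missed the threshold (adjusted p = 0.0951). Of the lists that had missed the threshold, the erythrocyte list passed it in 10 of 24 settings, the NF-kappaB list in 6, the miR-30 family in 5 and the let-7 family in 2. Without a filter the tubule, miR-17 cluster, endothelium, p53 and calcineurin lists passed it as well, and the fibrosis-restraining list passed with its direction turned (0.00209). The lowest adjusted p of the fibrosis-promoting, leukocyte and NF-kappaB lists came from that setting too. Most miRNAs compared there were detected on no array, so those lowest values do not measure a list's strength.

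The camera direction of lists past no threshold in the settings as reported turned as follows, with the adjusted p: fibrosis-restraining with normexp (0.378), quantile normalization (0.931) and the value table (0.843), and the miR-200 family with normexp (0.976), no filter (0.0816) and detection on all 8 arrays (0.964). The endothelium list turned with quantile normalization (0.783), the 75th percentile of all probes (0.913), median scaling (0.714), no scaling (0.989), total gene signal (0.954), without both arrays (0.512) and with the covariate (0.550). The tubule list turned without both arrays (0.970) and with the covariate (0.552), the miR-17 cluster without both arrays (0.970), the erythrocyte list with the covariate (0.799, without miR-451a itself), and the p53 list with detection on all 8 arrays (0.779), total gene signal (0.963), without both arrays (0.970) and with the covariate (0.799). Leaving out 1 array turned the fibrosis-restraining list (0.392 to 0.981 over the arrays), the tubule list (0.465 to 0.958), the miR-200 family (0.514 to 0.978) and the endothelium list (0.514 to 0.978). The cause was not tested.

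With the replicate number, which equals the slide column, as a block 0 miRNAs and 3 lists passed the threshold (31 miRNAs at an unadjusted p under 0.05, limma). Same-numbered arrays deviated together at 0.11, 0.14, 0.11 and 0.09, and 1 number of 4 correlated best with itself. As 1 of these correlations is under 0.1 and no label names a shared source, the numbers were not taken as pairs. A block for slide or scan was not run, as there was 1 of each.

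No scaling and the value table moved the median difference of all tested miRNAs to 0.19, against 0.04, and turned named miRNAs that had missed the threshold. These were, without scaling, miR-30c-2-3p (0.047), miR-30e-5p (0.063), miR-29b-3p (0.074), miR-7a-5p (0.085), miR-128-3p (0.093), miR-29a-3p (0.10) and miR-126a-3p (0.12). In the value table, miR-200b-5p (0.029), miR-30c-2-3p (0.053), miR-30e-5p (0.061), miR-29b-3p (0.078), miR-7a-5p (0.090), miR-29a-3p (0.11) and miR-126a-3p (0.12) turned. Without both arrays, where the median of all tested miRNAs was -0.081, miR-125b-5p (-0.017), miR-19b-3p (-0.032), miR-192-3p (-0.040), miR-194-5p (-0.048), miR-192-5p (-0.061) and miR-141-3p (-0.063) turned. So did miR-192-3p with normexp (-0.047), miR-28a-5p with total gene signal (-0.038) and miR-141-3p with the covariate (-0.0030). Leaving out 1 array gave ranges across 0 for miR-126a-3p (-0.16 to 0.0033, above 0 without control 1) and, below 0 without tacrolimus 4, for miR-19b-3p (-0.011 to 0.16), miR-192-5p (-0.020 to 0.17), let-7b-5p (-0.027 to 0.15) and miR-141-3p (-0.043 to 0.17). Scaling was redone here too, and without tacrolimus 4 the median of all tested miRNAs was -0.064. The smallest unadjusted p of a turned value was 0.562. Of the other 37 named miRNAs, miR-551b-3p, miR-338-3p, miR-223-3p and miR-486a-5p passed the threshold in 9 combinations. Signal over background limits the dim miRNAs: 829 were not tested.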

Other observations

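Of the 829 miRNAs that the tests left out, 801 were detected on no array, 23 on more tacrolimus than control arrays and 3 on more control than tacrolimus arrays, which was not tested. miR-146b-5p, a miRNA induced in inflammation, miR-34c-5p, a target of p53 made from one transcript with miR-34b, and miR-3072-5p were detected on 3 tacrolimus and 0 control arrays, were the 3 miRNAs with that count, and were chosen after their values were seen, while 0 miRNAs were detected on 3 control and 0 tacrolimus arrays. Without control 1 and tacrolimus 4, miR-146b-5p entered the test and was the 1 miRNA past the threshold. It entered through detection on tacrolimus arrays alone, since 0 control arrays detected it. A higher signal was thus built into that subset, and the call is not support for a rise. More miRNAs were detected on tacrolimus 1, 2 and 3 (209, 217 and 201) than on the control arrays (184, 197, 157 and 188), and fewest on tacrolimus 4 (147).

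Probes for the mouse cytomegalovirus miRNAs M23-1-5p and m88-1-3p gave a signal on all 4 arrays of both groups. The differences between tacrolimus and control kidneys were -0.33 and -0.22 after scaling, and were not tested. These signals are not evidence of virus, since cross-hybridisation of other RNA was not excluded. A probe for m22-1 of the same virus was detected on 2 control and 3 tacrolimus arrays.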
